A study of Mus musculus with 6 samples.

How the data were processed

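RNA was sequenced from 6 samples of immortalized mouse keratinocyte lines, 3 libraries of MK-546 (Control, no α3 integrin) and 3 of MK-546-ha3A (3A, human α3 restored). Per the labels' protocols, cells grew in full medium on collagen-coated 10 cm dishes to about 50 to 80% confluence. The design text gives an incubation temperature of 33 °C and 8% CO2. Cells were detached with trypsin substitute, pelleted and frozen, and a company isolated the RNA and made and sequenced the libraries. No density, passage or harvest date is given per sample in the sources used here.

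The deposited table holds raw read counts per gene, whole numbers for 49315 mouse Ensembl gene IDs in 6 libraries, with no normalization. Per the submitters' processing notes, the tools Trim Galore, featureCounts, edgeR and limma and the builds mm10, GRCh38 and hg38 were named, without versions or roles. The series' design text adds quality control with FastQC and MultiQC. The aligner, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be divided in unknown ways. The role of the human builds is likewise not given. The restored α3 is human, so some of its reads may have been counted on mouse Itga3.

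Gene symbols, positions, lengths and GC content came from GENCODE M21 (GRCm38, the assembly of mm10). Of the IDs, 49056 matched and 259 did not. The unmatched IDs held between 0.00903% and 0.0123% of a library's counts. All IDs entered the total counts, and library sizes for the test were summed over the genes that passed the low-count filter. All positions are 1-based. Total counts per library ranged from 25634204 to 36245240. At this depth a gene with 0 counts in the 3 libraries of 3A is bounded by a floor of 3 counts over the group (0.0277 CPM). Ratios of genes with 1 to 3 counts in a group are given with 95% exact binomial counting intervals.

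Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, estimateDisp, glmQLFit and glmQLFTest with default options, group as the only term). P-values were adjusted by the Benjamini-Hochberg method over the 13704 genes that passed the filter, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM for correlations and principal components a prior count of 1. The common biological coefficient of variation was 0.264, and the median log2 fold change over all tested genes was -0.02. Replicate pairs were compared by a chi-square of their counts over genes. The chi-square per degree of freedom ranged from 15.8 (3A 2 with 3A 3) to 315 (Control 1 with Control 3), so no pair agreed within sampling noise.

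Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The 26 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. At the threshold, 9 lists passed. With an estimated correlation 0 passed (limma camera, lowest adjusted p = 0.136, with 2 lists at an unadjusted p under 0.05), and by fry's directional test, which does not compare a list with other genes, 13 passed. The rule for names took Itga3, Itgb1, Cstf3 and Mmp9. It added the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, leaving out predicted or unnamed genes. It also took up to 4 called members with the smallest p from each list. List members that were not called could be named with their value. Results for a few single genes are not reported here.

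Alternatives were scaling by relative log expression, by library size alone or by upper quartile, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, the replicate number as a block, an adjusted p under 0.01, a test of changes beyond 1.5-fold, and each library left out in turn. Covariate adjustment for the mitochondrial mRNA share, and per-library offsets removing trends on GC content and transcript length (mgcv 1.9.3), were added after seeing the data. GC content and length were known for 99.7% of the tested genes.

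The pipeline was tested on simulated counts for the comparison of 3A with Control (13514 genes, 200 changed). It recovered 28% of 2-fold and 96% of 4-fold changes, and 15 of its 139 calls (10.8%) were false. Camera found a raised list, made of changed genes, and did not call an unchanged list. The simulated genes varied independently, so this does not show how camera behaves on lists of correlated genes. The simulated libraries also held no structure that crosses the groups, as the real libraries do. The shares recovered and falsely called may therefore differ in the real data.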

Results

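Gene-level read counts were obtained from immortalized mouse keratinocytes (MK cells), a skin-derived epithelial line. The Control group was the line MK-546, which lacks the α3 integrin subunit. The 3A group was MK-546-ha3A, the same cells reconstituted with human α3. Each group had 3 libraries, named here Control 1 to 3 and 3A 1 to 3. The total counts were 29685248, 30919348 and 25634204 in Control 1, 2 and 3, and 34177002, 36245240 and 35242818 in 3A 1, 2 and 3. Of the 49315 mouse genes counted, 13704 passed the low-count filter and were tested.

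The comparison of 3A with Control addressed how transcript levels depend on α3β1, a laminin-binding integrin, with Cstf3, a cleavage stimulation factor subunit used in mRNA 3' end formation, and the gelatinase gene Mmp9 as the genes named by the study. Cstf3 mRNA was 2.02-fold higher in 3A, whereas Mmp9 mRNA had the same mean level in both groups. By camera with its preset correlation, matrix protease and cholesterol synthesis genes were higher in 3A as groups, and interferon-stimulated genes and genes of the unfolded protein response were lower. None of these 4 lists passed with an estimated correlation (adjusted p = 0.423, adjusted p = 0.439, adjusted p = 0.136 and adjusted p = 0.423 with an estimated correlation, in this order). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1031 genes were higher and 1013 lower in 3A at an adjusted p under 0.05, of which 682 and 668 changed by 2-fold or more. The 3 libraries of each group did not overlap for 4951 genes (36.1% of those tested, against an average of 10% for exchangeable libraries). This share does not test the groups, since a split of the libraries that crosses the groups called 2099 genes. The genes without overlap included 2043 of the 2044 called genes, which the test on the same values largely implies.

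The size of these lists depended on single libraries. Control 1 correlated with Control 2 and Control 3 at r = 0.957 and 0.953 across genes, compared with 0.988 between Control 2 and Control 3, and it correlated with 3A 2 at 0.955 (genes are not independent replicates). Without Control 1 the test called 3751 genes higher and 3690 lower, including all 2044 genes called with 6 libraries. Leaving out Control 2, Control 3, 3A 1, 3A 2 or 3A 3 gave 413, 498, 640, 346 and 351 genes higher and 432, 489, 654, 318 and 319 lower, respectively. Each group was a single cell line, so α3 expression and descent of the line were confounded. Nothing in the labels says that the replicates were separate cultures, and the p-values then measure only the spread between these samples, which may be technical.

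**Figure D1:**
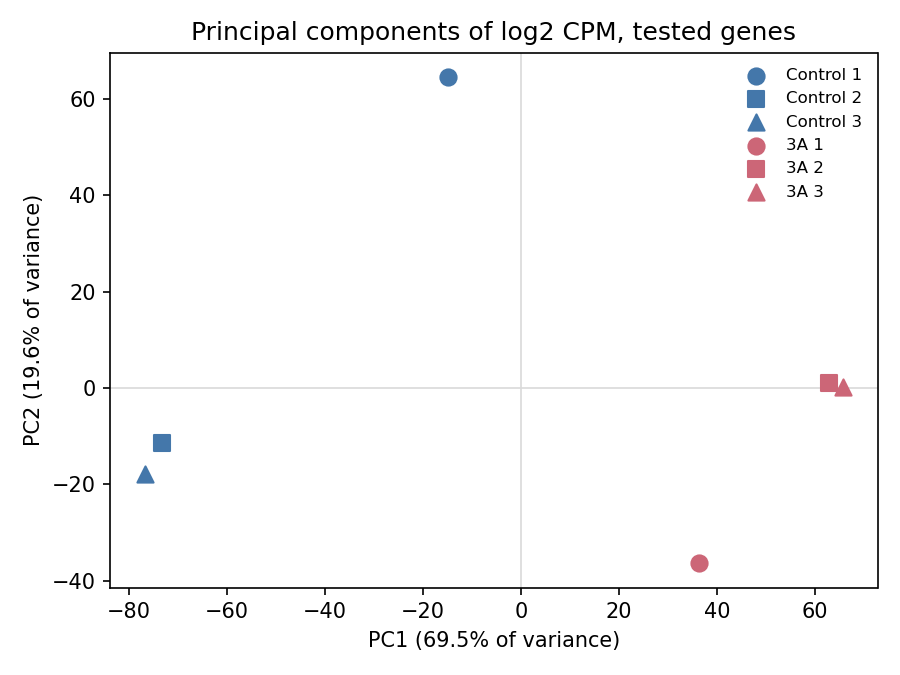
Principal components of log2 CPM over the 13704 tested genes, with one symbol per library; the axes are unitless scores and give the percent of variance. PC1 (69.5%) separates 3A from Control, with Control 1 at -14.9, Control 2 at -73.3 and Control 3 at -76.7. On PC2 (19.6%) Control 1 lies at 64.5, apart from Control 2 at -11.4 and Control 3 at -17.9. There 3A 1 lies at -36.4, apart from 3A 2 at 1.06 and 3A 3 at 0.142.

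Itga3, the gene altered in these lines, lies on the minus strand of chromosome 11 at 95044474 to 95076801 (GRCm38, the same assembly as mm10). It had 1007, 1220 and 1062 counts in Control 1, 2 and 3 and 2807, 2633 and 2064 counts in 3A 1, 2 and 3. Its level was 39.6 ± 6.84 CPM (mean ± SD, n = 3) in Control and 69.4 ± 11.5 CPM in 3A, a log2 fold change of 0.81 (SE 0.20, edgeR adjusted p = 0.0362). Reads from the human transgene can be assigned to the mouse gene, and a count over the whole gene does not show which exons the Control transcripts contain, so these counts check neither the deletion nor the transgene. The adjusted p was 0.0114 without Control 1 and between 0.0668 and 0.139 when any other library was left out. Itgb1, which encodes the β1 partner of α3 (chromosome 8, 128685654 to 128733200), had 500 ± 77.2 CPM in Control and 665 ± 131 CPM in 3A, a difference that did not pass the test (log2 fold change 0.41, edgeR adjusted p = 0.196). Without Control 1 the Itgb1 log2 fold change was 0.56 and passed (edgeR adjusted p = 0.0323).

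Cstf3 (chromosome 2, 104590523 to 104665429, plus strand) had 27.4 ± 9.66 CPM in Control and 55.3 ± 7.18 CPM in 3A (SD, n = 3). Its log2 fold change was 1.01 (SE 0.26, edgeR adjusted p = 0.0420), and all 3 libraries of 3A lay above all 3 of Control. The highest Control value, 38.5 CPM, was that of Control 1, against 22.0 and 21.5 CPM in Control 2 and Control 3. The log2 fold change was 1.36 (edgeR adjusted p = 0.000762) without Control 1. Leaving out any other library gave log2 fold changes from 0.87 to 1.12 that no longer passed (edgeR adjusted p from 0.0678 to 0.158). With each library's mitochondrial mRNA share as a covariate the log2 fold change was 0.60 (edgeR adjusted p = 0.0175). Mmp9 (chromosome 2, 164940780 to 164955850, plus strand) had 10.9 ± 1.96 CPM in Control and 10.9 ± 1.27 CPM in 3A. Its log2 fold change of -0.0050 (95% confidence interval -0.46 to 0.45, edgeR adjusted p = 0.989) lay within the spread between replicates, and its sign changed with the scaling. Counts summed over a gene do not show which polyadenylation site was used, so the choice of Mmp9 3' ends was not analysed here.

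**Figure D2:**
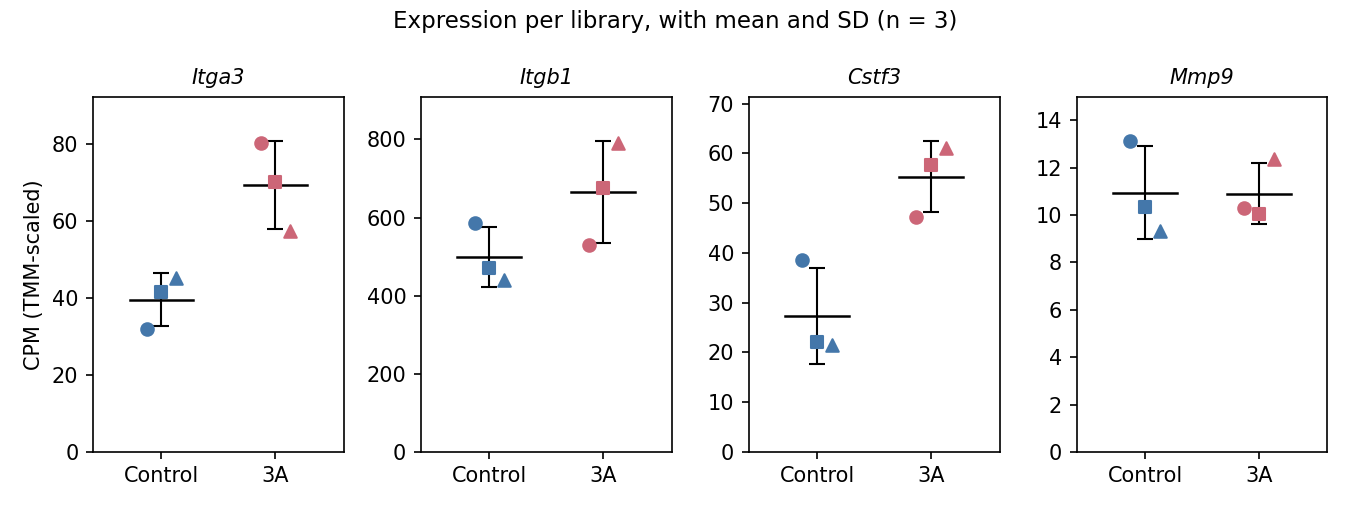
Expression of Itga3, Itgb1, Cstf3 and Mmp9 in each library in CPM after TMM scaling (circle, square and triangle for replicates 1, 2 and 3), with the group mean (horizontal line) and SD (error bar, n = 3). The groups do not overlap for Itga3 and Cstf3, and Mmp9 has a mean of 10.9 CPM in both.

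Among cleavage and polyadenylation factors, 3 of 24 tested genes rose and 0 fell. Besides Cstf3, these were Clp1, a subunit of cleavage factor II (log2 fold change 0.47), and Cstf2t, a paralog of the RNA-binding CstF subunit (0.98). At an unadjusted p under 0.05, edgeR had 6 higher and 1 lower, and DESeq2 called 6 and 0. Adjusted over the list alone, 0 rose and 0 fell by edgeR, and the list as a whole did not differ from other genes (camera adjusted p = 0.583). The 3 called factors had edgeR adjusted p between 0.0420 and 0.0478. Without Control 1, 9 factors were higher and 5 lower by edgeR, and none was called when any other library was left out. Of 42 splicing regulators, 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.150). The risers included Hnrnpm (0.88), Srsf1 (0.83), Tra2a (0.80) and Srsf3 (0.69). With the mitochondrial mRNA share as a covariate, 12 were higher and 1 lower and the splicing list passed camera (adjusted p = 0.0110), as it did with no low-count filter (adjusted p = 0.0219). Its camera adjusted p was 0.423 with an estimated correlation and group as the only term. DESeq2 called 11 splicing regulators higher and 2 lower. Without Control 1, 19 splicing regulators were higher and 9 lower, and without any other library at most 4 and 1.

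Genes for matrix proteases and their inhibitors were higher in 3A: of 32 tested, 12 rose and 2 fell (12 and 3 adjusted over the list alone), with a median log2 fold change of 0.68. Without Control 1, 17 were higher and 3 lower, and without any other library 7 to 11 and 1. The list passed camera with its preset correlation (adjusted p = 0.000445) but not with an estimated correlation (adjusted p = 0.423). Plau, which encodes urokinase, rose from 342 ± 38.9 to 1341 ± 128 CPM (SD, n = 3; log2 fold change 1.97, SE 0.17, edgeR adjusted p = 0.000846). The stromelysin genes Mmp3 and Mmp10 rose by 3.03 and 2.02 on the log2 scale, to 5.56 and 8.30 CPM. Serpine2, a protease inhibitor gene, fell by 2.11. Of the 7 genes fixed as tied to α3β1 in keratinocytes by earlier work, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.00260; adjusted p = 0.423 with an estimated correlation). Il1a rose from 459 ± 79.1 to 1950 ± 290 CPM (log2 fold change 2.09, SE 0.21). Fbln2, encoding the matrix protein fibulin-2, rose by 1.96, and Prl2c3, a proliferin gene, by 2.32. Reads on Prl2c3 are uncertain because proliferin genes are near-identical copies. Ptgs2, encoding cyclooxygenase-2, fell by 1.46 on the log2 scale. Mmp9 was also a member.

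The other adhesion and matrix lists held called members in both directions. Over all tested genes, 2044 of 13704 were called with 6 libraries, and 7441 genes were called without Control 1. List counts are to be read against these totals. Of 14 integrin subunit genes (Itga3 not among them), Itgb2 rose (log2 fold change 1.64, at 1.49 CPM in 3A), while Itgb5 and Itgb7 fell by 0.58 and 0.59 (camera adjusted p = 0.388; 1 and 2 adjusted over the list alone). Of 39 focal adhesion and actin adaptor genes, the adaptor gene Nedd9 (2.25) and the kindlin gene Fermt2 (1.10) rose and Cnn2 (-0.76) fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.208). For this list DESeq2 called 4 higher and 2 lower, and 5 and 4 were called with the mitochondrial mRNA share as a covariate and 4 and 1 with offsets for GC content and length. Among 18 laminin and basement membrane genes, 3 rose, including Col4a1 (1.77), and 4 fell, including Fbln1 (-1.44) and Lamb2 (-0.80), with 5 and 6 adjusted over the list alone. This list's median log2 fold change was -0.08 and its mean 0.07, with camera pointing up (adjusted p = 0.806). With offsets for GC content and length 5 of them were higher and 1 lower, and Lamb2 was not called (adjusted p = 0.0616), while DESeq2 called 5 and 6. Among 15 interstitial matrix genes, 5 rose, including Sparc (1.77) and Fn1 (1.43), and 2 fell, Tgfbi (-3.76) and Thbs2 (-2.99), with 6 and 2 adjusted over the list alone (camera adjusted p = 0.507). Without Control 1, 7 integrin subunits were higher and 2 lower, 15 and 3 focal adhesion genes, 7 and 6 laminin and basement membrane genes and 6 and 2 interstitial matrix genes. Without any other library, at most 1 integrin subunit was higher and none lower. The focal adhesion list then had 2 higher and at most 1 lower, the laminin and basement membrane list 2 to 3 and at most 1, and the interstitial matrix list 1 to 3 and 2.

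Cell junction and hemidesmosome genes were lower in 3A as a list (camera adjusted p = 0.0186; adjusted p = 0.423 with an estimated correlation), with 2 of 26 higher and 6 lower (2 and 7 adjusted over the list alone). The list did not pass without Control 1 (adjusted p = 0.0919) or without 3A 1 (adjusted p = 0.110). The desmosomal genes Dsc3 and Pkp2 fell from 86.1 ± 43.3 to 0.833 ± 0.312 CPM and from 15.2 ± 0.954 to 1.44 ± 0.233 CPM (SD, n = 3; log2 fold changes -6.68 and -3.40). The connexin gene Gjb5 (-1.56) and the desmosomal plaque gene Pkp1 (-0.92) fell as well. Of 22 basal keratinocyte genes, 3 rose, including the EGF family ligand Areg (2.43) and the transferrin receptor gene Tfrc (1.53), and 5 fell, including Krt15 (-4.18) and Bcl11b (-2.82), with 3 and 7 adjusted over the list alone (camera adjusted p = 0.224). The abundant basal keratin genes Krt5 and Krt14 had 4564 and 3509 CPM in Control and 3190 and 2810 CPM in 3A and were not called. Among 27 differentiation genes, 3 rose, including Aqp3 (0.96), and 6 fell, including Sbsn (-2.26), Krt16 (-1.88) and Dmkn (-1.54), with 4 and 9 adjusted over the list alone (camera adjusted p = 0.150). Mesenchymal transition genes went both ways, with 4 of 21 higher, including Lgals1, and 4 lower, including the transcription factor genes Foxc1 (-1.67), Snai2 (-0.89) and Twist2 (-1.66); 4 and 7 were called adjusted over the list alone (camera adjusted p = 0.936). With the mitochondrial mRNA share as a covariate, 11 junction genes and 8 basal keratinocyte genes were lower. Without Control 1, 6 junction genes were higher and 9 lower, 5 and 11 basal keratinocyte genes, 5 and 11 differentiation genes and 6 and 9 mesenchymal transition genes. Without any other library, at most 2 junction genes were higher and 3 to 4 lower, 1 to 2 and 2 to 3 basal keratinocyte genes, 1 to 2 and 3 to 4 differentiation genes, and 1 to 3 and at most 3 mesenchymal transition genes.

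Interferon-stimulated genes formed the list with the smallest camera p, pointing down (adjusted p = 2.13e-09; adjusted p = 0.136 with an estimated correlation). Of 44 tested, 1 rose and 18 fell (1 and 24 adjusted over the list alone), with a median log2 fold change of -0.64. Without Control 1, 4 were higher and 28 lower, and without any other library at most 1 was higher and 9 to 14 were lower. The riser was Iigp1 (log2 fold change 0.98), named after its value was seen. Ifit3 fell from 213 ± 28.3 to 28.8 ± 5.39 CPM (SD, n = 3; log2 fold change -2.89, SE 0.20, edgeR adjusted p = 0.000452). Dhx58, which encodes a cytosolic RNA sensor, fell by 4.03, Oas2 by 3.16 and Ifi27l2a by 3.80. Counts on Ifit3 are uncertain because it has a near-identical neighbour gene. Cytokine and chemokine genes were mixed, with 7 of 31 higher and 7 lower (10 and 8 adjusted over the list alone; camera adjusted p = 0.456); Il1a was among the risers, and Lcn2 (-2.38) and Ccl8 (-3.95) fell, as did Ptgs2. With the mitochondrial mRNA share as a covariate 13 of the 31 were higher and 6 lower (camera pointing up, adjusted p = 0.0861), with offsets for GC content and length 10 and 7, and by DESeq2 10 and 7. Among 30 secreted growth and angiogenic factors, 7 rose, including Sema3e (2.02), and 5 fell, including Vegfd (-2.80), with 9 and 9 adjusted over the list alone. This list's median (-0.05) and mean (-0.07) were negative while camera pointed up (adjusted p = 0.854). DESeq2 called 8 higher and 8 lower. Without Control 1, 11 cytokine genes were higher and 10 lower, and 10 and 12 growth factor genes. Without any other library these were 3 to 5 and 4, and 3 to 4 and 1 to 4.

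All 5 called members of the cholesterol synthesis list rose, of 25 tested (9 higher and 0 lower adjusted over the list alone; median log2 fold change 0.56; camera adjusted p = 0.000183; adjusted p = 0.439 with an estimated correlation). Acat2 rose from 89.0 ± 4.74 to 173 ± 3.85 CPM (SD, n = 3; log2 fold change 0.96, SE 0.13), Cyp51 by 0.81, Pmvk by 0.70 and Tm7sf2 by 2.12. Over this list the mean log2 CPM was 6.49, 6.02 and 5.95 in Control 1, 2 and 3 and 6.57 in 3A 1, with 3A 2 and 3A 3 higher, so Control 1 lay close to 3A 1. DESeq2 called 10 members higher. Without Control 1, 17 members rose, and without any other library 2 to 3. Of 31 genes of the unfolded protein and amino acid stress responses, 0 rose and 10 fell (0 and 13 adjusted over the list alone; camera adjusted p = 0.00236; adjusted p = 0.423 with an estimated correlation). Hspa5, encoding the endoplasmic reticulum chaperone BiP, fell from 1898 ± 179 to 842 ± 82.5 CPM (log2 fold change -1.17, SE 0.17), Ddit3 by 1.48, Pdia4 by 1.11 and Syvn1 by 0.95. Without Control 1, 4 of these stress genes were higher and 15 lower, and without any other library 1 to 5 were lower. The cell cycle list pointed up, with 3 of 47 genes higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.0164; adjusted p = 0.423 with an estimated correlation). The 3 were Rrm2 (1.00), Rrm1 (0.62) and Birc5 (0.55), and the list did not pass without 3A 1 (adjusted p = 0.0591) or with offsets for GC content and length (adjusted p = 0.0516). More cell cycle genes were called in other fits, with 26 higher and 2 lower without Control 1, 14 higher by DESeq2, 7 with the mitochondrial covariate and 6 with the offsets; without any other library 1 was higher.

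**Figure D3:**
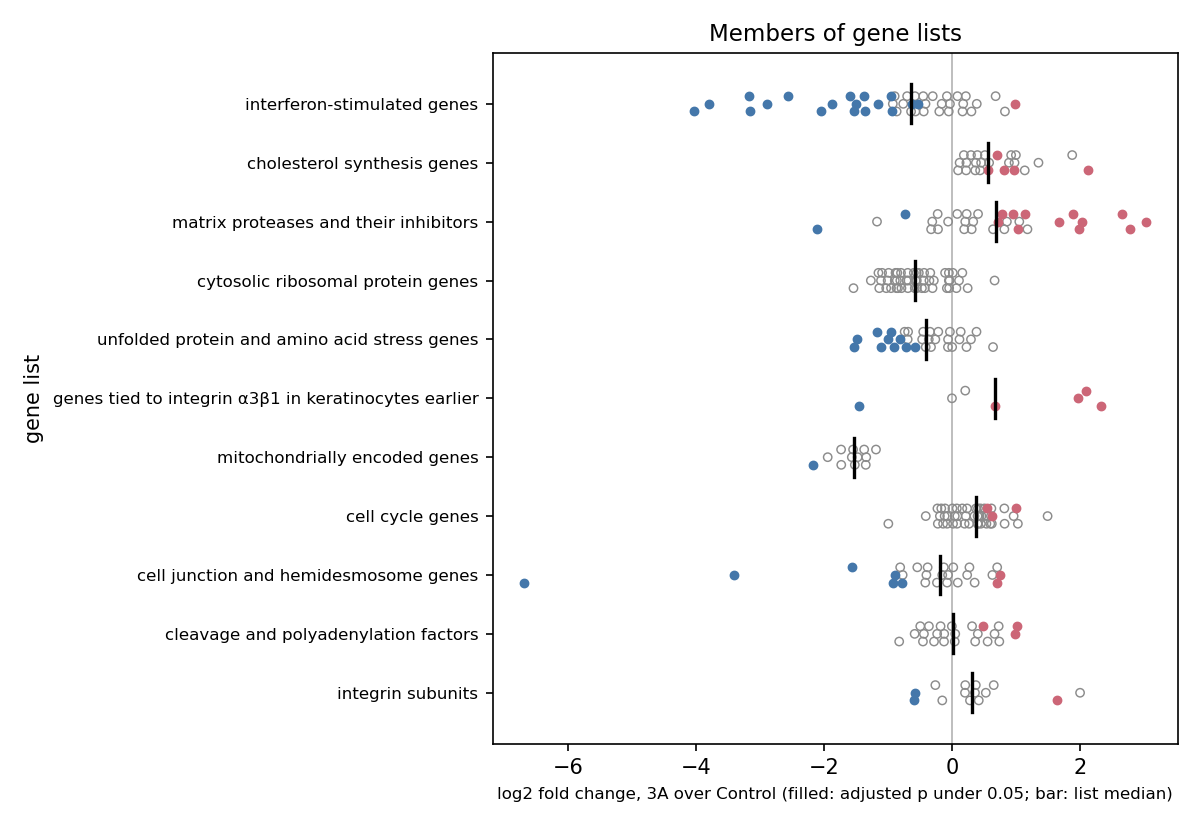
Log2 fold changes (3A over Control) of the tested members of 11 gene lists: the 9 that passed camera with its preset correlation, ordered by adjusted p, then the cleavage and polyadenylation factors and the integrin subunits. Each symbol is a gene, filled where its edgeR adjusted p was under 0.05 (red higher and blue lower in 3A), and the black bars are list medians, such as -0.64 for interferon-stimulated genes and 0.68 for matrix proteases.

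The remaining signalling and stress lists did not pass camera with group as the only term. With the mitochondrial mRNA share as a covariate the p53 target list passed, pointing down (adjusted p = 0.0241), with 8 members lower. With an estimated correlation and group as the only term, its camera adjusted p was 0.423. Immediate early and MAPK feedback genes had 5 of 31 higher, including Fosb, Fos (1.34), Spred1 (0.73) and Ier3 (0.63), and 2 lower (5 and 2 adjusted over the list alone; median -0.20, mean 0.02, camera pointing up with adjusted p = 0.836). YAP and TAZ target genes had 2 of 25 higher, including Lhfpl2 (2.31), and 6 lower, including F3 (-2.13), Rbms3 (-3.53) and Dlc1 (-0.99), with 3 and 7 adjusted over the list alone (camera adjusted p = 0.363). Of 30 p53 target genes, 0 rose and 5 fell, among them Cd82 (-2.26), Pmaip1 (-1.44), Psrc1 (-1.16) and Fas (-0.78), with 0 and 5 adjusted over the list alone (camera adjusted p = 0.137). Of 31 hypoxia and glycolysis genes, Ldha rose (0.78) and Egln3 (-5.98), Slc2a1 (-0.98) and Aldoc (-0.94) fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.222). Of 23 NRF2 target genes, Me1 rose (0.56) and Gsta4 (-3.02), Nqo1 (-1.71) and Gclc fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.175). Counts also moved between fits. By DESeq2, 5 hypoxia and glycolysis genes were higher and 5 lower, 2 and 8 NRF2 targets and 1 and 8 p53 targets. With the mitochondrial covariate 3 hypoxia and glycolysis genes were higher and 8 lower, 4 and 3 NRF2 targets and 8 and 2 immediate early and MAPK feedback genes. With offsets for GC content and length these were 4 and 6, 2 and 4, and 5 and 2. Without Control 1, 7 p53 targets were higher and 8 lower, 9 and 6 immediate early and MAPK feedback genes, 8 and 7 YAP and TAZ targets, 7 and 10 hypoxia and glycolysis genes and 5 and 9 NRF2 targets. Without any other library, 1 to 2 immediate early and MAPK feedback genes were higher and at most 1 lower, and at most 2 YAP and TAZ targets were higher and 2 to 3 lower. No p53, hypoxia and glycolysis or NRF2 member was then higher, and 2 to 3, 2 to 3 and 3 were lower.

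The largest rises among genes with a mean of at least 5 CPM were those of Gatm, which encodes an enzyme of creatine synthesis, Exoc3l4, Lgals1, Ly9, Adgrf5, Prrg1, Txnip and Neurl3. Their log2 fold changes ranged from 3.89 (Neurl3) to 5.72 (Gatm). Gatm rose from 1.22 ± 0.619 to 65.8 ± 10.7 CPM (SD, n = 3), and Lgals1, encoding galectin-1, from 0.978 ± 0.449 to 28.0 ± 9.41 CPM. Txnip, a thioredoxin-interacting protein gene, rose from 1.99 ± 0.141 to 32.2 ± 4.13 CPM. Among the largest falls, Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, had 12.4 ± 3.94 CPM in Control and 0 counts in all 3 libraries of 3A. Against a floor of 3 counts over the group, it was at least 439.6-fold lower. Akip1 had 2 counts over the 3 libraries of 3A and 2710 over those of Control, a depth-scaled ratio of 1740.1 (95% counting interval 481 to 14376). Slc25a13 had 3 and 3126 counts, a ratio of 1338 (457 to 6492). These floors and intervals cover counting error only. Pgpep1, Pacs1, Dsc3, Pbxip1 and the RNA-binding protein gene Igf2bp3 fell with log2 fold changes from -8.61 (Pgpep1) to -5.47 (Igf2bp3). All 16 of these genes had edgeR adjusted p of 0.00157 or less.

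Mitochondrially encoded transcripts did not split by group alone. They took 1.16%, 4.16% and 4.69% of the counts in Control 1, 2 and 3 and 1.58%, 1.23% and 1.30% in 3A 1, 2 and 3. Their list pointed down (median log2 fold change -1.53; camera adjusted p = 0.00555; adjusted p = 0.647 with an estimated correlation), with mt-Co2 (-2.18) the 1 called member of 12 (0 higher and 9 lower adjusted over the list alone; 0 and 10 at an unadjusted p under 0.05; 0 and 10 called by DESeq2 and 0 and 0 by limma-voom). The mt-Co2 call was marginal (edgeR adjusted p = 0.0499), its groups overlapped, and it was lost under every other scaling and when any library but Control 1 was left out. Without Control 1, edgeR called 13 mitochondrial members lower, more members having passed the filter, and with offsets for GC content and length 7. Cytosolic ribosomal protein genes took 6.22%, 9.05% and 9.33% of the Control counts and 6.78%, 5.78% and 5.73% of the 3A counts. Of these, 0 of 50 were called by edgeR in either direction (0 adjusted over the list alone as well; 1 higher and 21 lower at an unadjusted p under 0.05; 1 and 11 called by DESeq2 and 0 and 0 by limma-voom). Without Control 1, edgeR called 1 ribosomal protein gene higher and 38 lower, and with the offsets 7 lower. The list pointed down (camera adjusted p = 0.00234; adjusted p = 0.647 with an estimated correlation). Of 9 replication-dependent histone genes, Hist1h1c (-1.76) and Hist1h2bc (-2.37) fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.208), and 4 were lower without Control 1 and 1 to 2 without any other library. Markers of other cell types were few. The immune marker Ptprc had 0.011 CPM in Control, the fibroblast marker Dcn 0.011 CPM and the endothelial marker Pecam1 0.139 CPM, while Cd74 (50.6 CPM in Control, 36.4 in 3A), Cd68 (16.7 and 10.9) and Egfl7 (21.5 and 21.2) were present in both groups. Of the tested markers, Twist2 (1 of 4 fibroblast genes) and Pmel (-1.05; 1 of 2 melanocyte genes) fell, Flt1 (0.91; 1 of 4 endothelial genes) rose, and 0 of 3 immune genes were called by edgeR, DESeq2 or limma-voom, all 3 being lower at an unadjusted p under 0.05. Adjusted over each list alone, 0 and 1 fibroblast, 0 and 2 melanocyte, 0 and 3 immune and 1 and 0 endothelial markers were higher and lower. Without Control 1, 2 fibroblast and 3 immune markers were lower, and without Control 2, Control 3, 3A 2 or 3A 3 no marker of another cell type was called.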

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

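Adjustment for the mitochondrial mRNA share and for GC content and length was chosen after seeing the data, and the other alternatives were fixed before. No gene called in the comparison was called in the opposite direction under any of them. The counts of genes higher and lower in 3A (1031 and 1013) stayed within 1.5 times under 3 other scalings, 2 other filters, limma-voom, robust quasi-likelihood and the GC and length offsets. They were 1678 and 1887 with DESeq2, 1587 and 1566 with the mitochondrial covariate, 364 and 352 at an adjusted p under 0.01, and 417 and 419 for changes beyond 1.5-fold, where a stricter criterion shortens the list by construction. Leaving out one library at a time gave 346 to 3751 genes higher and 318 to 3690 lower, and 329 to 1762 higher and 311 to 1919 lower at 2-fold or more. The highest values came without Control 1 and kept all 2044 calls. The lowest came without 3A 2 or 3A 3. With 1 library fewer in a group, a loss of calls follows partly from the smaller sample.

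Labels give both groups replicate numbers 1 to 3, without saying that a shared number marks a shared day or batch. Deviations from the group means of same-numbered libraries correlated at -0.787, -0.805 and -0.558 over 9405 genes, and no library matched its own number best. The signs followed the difference of Control 1, 3A 2 and 3A 3 from Control 2, Control 3 and 3A 1. These correlations therefore cannot exclude a smaller effect shared by number. With a replicate block, 142 genes were higher and 146 lower, all with changes of 2-fold or more. The log2 fold changes under the block were 0.81 for Itga3 (edgeR adjusted p = 0.204), 1.06 for Cstf3 (adjusted p = 0.174) and 0.0036 for Mmp9.

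The Itga3 log2 fold change ranged from 0.69 to 0.94 and that of Cstf3 from 0.87 to 1.36 with one library left out, both called only without Control 1. Scaling by library size alone gave 1.06 for Cstf3 (edgeR adjusted p = 0.0629), a loss whose cause was not tested. Mmp9 was never called, and its log2 fold change turned positive with library size alone (0.052), no filter (0.022), the GC and length offsets (0.063) and some left-out libraries (-0.11 to 0.16 over all 6). Of the gene lists, 0 passed with an estimated correlation, and 7 to 9 passed with one library left out. The junction list was lost with limma-voom (adjusted p = 0.0973). The mitochondrial and ribosomal protein lists were lost with the mitochondrial covariate (adjusted p = 0.921 and 0.685) and by fry (0.207 and 0.198). The loss of the mitochondrial list under that covariate follows by construction, since the share is computed from its own protein-coding members. Under that covariate the splicing and p53 lists were gained (adjusted p = 0.0110 and 0.0241), and with no filter the splicing list (0.0219). Fry gained 6 lists, these and the basal keratinocyte, YAP and TAZ, hypoxia and NRF2 lists. Of 104 named called genes, 44 kept their call under the block, 64 to 104 with one library left out and 93 to 104 under the other alternatives run at the same threshold. Depth limits genes near the floor, where folds rest on a few counts.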

Other observations

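The tests in this part were chosen after the results were seen, except the list test of interferon-stimulated genes, the one on mitochondrial and ribosomal protein transcripts, the one on interferon-related genes outside the list, and the other splits of the libraries. Of 18 tested imprinted genes, 6 were lower in 3A, 1 was higher and 11 were not called, with no test against other genes (this group and the germline genes were named after some of their values were seen). Besides Cdkn1c, edgeR called Impact (log2 fold change -1.11), Igf2 (-1.86), Slc22a18 (-1.27), Zrsr1 (-1.79) and Kcnq1 (-2.04) lower and Peg13 (1.92) higher in 3A. The 11 not called went both ways. Igf2r (-0.63), Gnas (-0.52), Kcnq1ot1 (-2.81), Airn (-1.49), Snrpn (-0.10) and Phlda2 (-0.09) had negative log2 fold changes. Those of Peg3 (1.32), Nnat (1.28), Ndn (0.97), Mest (0.64) and Plagl1 (0.43) were positive. Slc22a18 and Kcnq1ot1 are the nearest expressed neighbours of Cdkn1c on chromosome 7, so the lower levels of these genes need not be separate events. Of 4 tested X-linked genes that were grouped as germline genes, 2 were higher, while Xlr3c (1.35) and Xlr3a (-0.80) were not called. The grouping is loose, and Xlr3a had 12.8 CPM in Control. Magea8 had 0 counts in Control and 5.25 ± 0.772 CPM (SD, n = 3) in 3A, at least 148-fold higher against a floor of 3 counts over the group. Rhox5, a homeobox gene, rose from 1.37 ± 0.670 to 13.0 ± 2.90 CPM. Chromosome 10 had the lowest median log2 fold change of chromosomes 1 to 19 and X (-0.24 over 486 genes; the others lay between -0.13 and 0.15).

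The 6 libraries make 10 splits into 3 and 3, so no share under 0.1 is possible. The real split called 2044 genes and the highest other split 2099, so 2 of the 10 splits called as many as the real one. The other split set Control 1, 3A 2 and 3A 3, whose deviations from the gene means rose with transcript length (Spearman rho 0.352, 0.257 and 0.213), against Control 2, Control 3 and 3A 1, where they fell with it (-0.339, -0.221 and -0.197), a structure of the samples that crosses the groups and whose source was not tested. The remaining 8 splits called 0 genes each by edgeR (12 to 380 at an unadjusted p under 0.05) and 0 or 1 by DESeq2. For gene lists, by camera with its preset correlation, the real split called 9 and each of the others 3 to 8, also where 0 genes were called, so 1 of the 10 splits reached the real value.

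Control 1 lay apart from the other Control libraries, 48.1% of the way from Control 2 and 3 towards 3A over all tested genes on the log2 scale. An admixture of 3A cells or RNA is argued against by 9 genes near silent in Control 2 and 3 and expressed in 3A. For these genes Control 1 lay, in CPM, a median of 0.579% of the way from Control 2 and 3 towards 3A. The highest of them reached 22.9%, and percentages on the CPM and log2 scales are not directly comparable. Smooth trends on GC content and length explained 17.3% of the variance of the difference, under the limit of 20% written after the value was known, so they may account for a part but not most of it. Without 194 mitochondrial and ribosomal protein genes Control 1 still correlated with Control 2 and 3 at 0.955, against 0.988 between Control 2 and Control 3. The difference was thus not confined to these genes. A correlation over all tested genes can hardly move when so few are left out. Whether different shares of these transcripts contribute to the difference therefore stays undecided. A difference in culture state, such as density within the stated 50 to 80% confluence, stays open and was not tested.

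Over the 3 libraries of 3A, 20 called genes with at least 1 CPM in Control had at most 3 counts in total; they lay on 9 chromosomes and include Slc25a13, Akip1, Cdkn1c, Fam149a and Rab19. The reverse held for 8 genes, among them Gm364 and Magea8. Loss of a chromosome segment holding several expressed genes would take neighbours along, and 10% of the 20 genes (2) had a neighbouring expressed gene that fell at least 8-fold. The test was to count against segment loss under 10%, so it stays undecided. For Prl8a1 and Cdkn1c the neighbour that fell more had log2 fold changes of -2.97 and -2.81, just short of 8-fold. Over the 20 genes the median log2 fold change of the neighbour that fell more, computed after that share was seen, was -0.33 (lower quartile -0.98). Whether restored α3 or the descent of the 3A line, for example through silencing fixed while the line was derived, may be the source cannot be told apart with 1 line per group.

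Interferon-stimulated genes were lower in 3A as a list by camera with its preset correlation (adjusted p = 2.13e-09; adjusted p = 0.136 with an estimated correlation). The library state tracked by the mitochondrial mRNA share is argued against as the whole cause, since all 18 lower members stayed called with that share as a covariate. The list median log2 fold change was then -0.48, against -0.64 without it. Of all 2044 called genes, 1867 (91.3%) also kept their call with this covariate. Keeping the call was thus not particular to interferon-stimulated genes. Trends on GC content and length are argued against as well, with a list median of -0.71 under offsets for both. Within the list, 2 classes covering 23 of the 44 tested members differed: 11 of 12 IFIT, OAS and MX genes fell (median log2 fold change -1.44), and 0 of 11 other members, Irf1 and genes of the guanylate-binding, immunity-related GTPase and antigen-processing families, did (median 0.16; Fisher exact two-sided p = 9.61e-06, descriptive only, since these classes were chosen after the values were seen), while the 21 members in neither class held the other 7 of the 18 lower genes (median -0.58). Family members outside the list did not bear out a difference between the classes, with 1 of 5 and 1 of 15 lower (Fisher exact two-sided p = 0.447), too few to exclude one, and whether α3 or line descent is behind the fall stays open.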
